A study of Mus musculus with 19 samples.

How the data were processed

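P19CL6 cells were sampled at days 1, 4, 7, 10 and 14 of differentiation, and 19 libraries were grouped by day, with 3 at day 1 and 4 at each later day. Libraries were made with the Illumina DGE Tag Profiling Kit, protocol version 2.1B, per the labels' protocols. Tags refer to genome build mm9 per the submitters' processing notes, and the aligner and the statistical test are not given in the sources used here. The design text says that the log2 table was filtered by FDR and is incomplete.

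The deposited data used were 4 tables, one for each later day against day 1. They hold, per gene, the authors' mean raw tag count over the libraries of each day, the deposited TPM (tag counts scaled to a common library total) of each day, and the authors' log2 ratio of the TPM values, later day over day 1. For 100% of genes the deposited mean raw count, times the number of libraries of the day, is a whole number within its 2 printed decimals, which allowed the summed tag counts per day to be recovered. The deposited TPM is 0.01 where the mean count is 0, and such values were read as 0. The smallest absolute log2 ratio in the deposited tables is 1.00. Columns headed P-Value and FDR, scores per the file headers, were not used for any test, because the deposited FDR exceeds 1 for 56.5%, 60.2%, 60.1% and 55.9% of genes at days 4, 7, 10 and 14. The tables hold 0 columns with values of a single library, so no test between replicates was possible, and genes that did not pass the authors' filter are not in them.

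A gene counted as risen or fallen where the authors' deposited table lists it. Fold (ratio) values were computed from the recovered tag sums and the group totals that the deposited counts and TPM imply, 17.4, 23.4, 23.4, 22.9 and 23.8 in units of 1e+06 tags, at days 1, 4, 7, 10 and 14. Intervals at the 95% level are exact (Clopper-Pearson for folds, Poisson for levels) and cover counting error only. Genes at 0 tags were set to a floor of 3 counts over the libraries of the day.

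Before the data were examined, 32 gene lists, the comparisons, the tests and the rule for naming genes were fixed. Of the symbols on the lists, 331 matched a gene in the tables, 1 matched through an older symbol and 326 were not in the tables. The lists cover pluripotency, primitive streak and early mesoderm, cardiac transcription factors, sarcomere, cardiac calcium handling and ion channels, smooth and skeletal muscle, endothelium and blood, endoderm, neural, epicardial and fibroblast, and epithelial genes. They also cover extracellular matrix, TGF-β components and targets, the BMP, Nodal, hedgehog, Wnt, Notch and retinoic acid pathways, primary cilium, endocytosis, cell cycle and its inhibitors, glycolysis, fatty acid oxidation, imprinted genes, immediate early and heat shock genes, Hox genes, ribosomal proteins and histones. Direction was tested by Fisher's exact test, two-sided, of members that rose or fell against all other listed genes, for lists with at least 5 members listed. Representation was tested by Fisher's exact test, two-sided, of members listed at a day among the 4213 genes listed at any day. In each family, p-values were adjusted by the Benjamini-Hochberg method over all lists and days, and 0.05 was the threshold.

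The named genes are, per comparison, the 8 with the largest rise and the 8 with the largest fall among genes with a standard symbol at or above the median abundance of the table, and up to 4 members of each list with the largest change at that abundance, or over the whole table where fewer than 2 pass it. Changes were ranked by the deposited log2 ratio, in which 0 tags count as 0.01 TPM. This favours genes at 0 tags at day 1 over genes with a larger fold as given here. Pou5f1, Nanog, Sox2, Nkx2-5, Gata4, Tnnt2, Myh6, Actc1, Tgfbr1, Tgfbr2, Smad2, Smad3, Smad4, Smad7, Ift88, Cltc and Eea1 were followed whether listed or not. Overlap between days was compared with the overlap of independent lists drawn from the 4213 genes. The symbol column is blank for 57, 57, 74 and 86 genes at days 4, 7, 10 and 14, and "not listed" means not listed under its symbol.

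The alternatives were restriction to genes at or above the median abundance, absolute log2 change of at least 1 or of at least 2, every entry counted, the most abundant entry per symbol, log2(TPM + 1), genes with at least 1 tag on each side, all genes of the reference table as background, medians over members listed at all 4 days, and symbols read from descriptions. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. They were tested on data simulated from the 2823 genes of the day 14 comparison, in which 200 genes were changed by known folds. Of 91 genes changed 3-fold, 92.3% were recovered, and of 109 changed 5-fold, 95.4%, with 0 called among unchanged genes and 96% of intervals covering the true fold. Calls in the simulation used a 2-fold limit and an adjusted counting p-value, whereas the results take the genes the authors listed. Each simulated gene had a minimum of day 1 tags and counting error only. Genes near 0 tags at day 1 and the error between replicates were therefore not tested. Of 200 random lists of 15 genes, 3% were called in error, and 100% of lists planted with mostly fallen genes were found. Lists of mostly risen genes were not planted, so the power to find them was not measured.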

Results

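P19CL6 is a mouse embryonal carcinoma line, a culture of undifferentiated tumour cells that can be driven to form beating heart muscle cells. RNA from these cultures was profiled at days 1, 4, 7, 10 and 14 of differentiation by digital gene expression tag profiling, in which a short sequence tag stands for each transcript molecule and tags are counted per gene. According to the design text, spontaneous beating was seen at day 14. The study's title places it in work on TGF-β signalling and endocytosis at the pocket of the primary cilium, the membrane fold from which this sensory organelle grows. There were 3 libraries at day 1 and 4 at each of the later days, 19 in all. The design text speaks of 4 replicates per day, and the deposited day 1 means are means over 3 libraries. The mean library held 5.81e+06 tags at day 1, 5.86e+06 at day 4, 5.84e+06 at day 7, 5.72e+06 at day 10 and 5.96e+06 at day 14.

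Each later day was compared with day 1. A gene is said to have risen or fallen where the authors' deposited table for that day lists it, and every listed gene differed at least 2-fold. A gene that is not listed has no value here and is not shown to be unchanged, and genes were matched to lists by symbol. Levels are the authors' means over the libraries of a day, in TPM, the tag count of a gene scaled to a common library total. The spread between replicate libraries cannot be computed from such means, so no p-value is given for a single gene. Folds were computed from the summed tags, and the 95% intervals in brackets (exact, Clopper-Pearson) cover counting error only, not the error between replicates. Where a gene had 0 tags at day 1, the fold was taken against a floor of 3 tags over the 3 libraries, or 0.172 TPM. Such a fold is written as at least that value. It leaves out counting error, and the lower limit of the exact 95% interval lies below it.

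The deposited tables for days 10 and 14 listed more genes than those for days 4 and 7, and rises outnumbered falls most at days 10 and 14. In the authors' deposited table for day 4, 899 genes rose and 880 fell, so that 50.5% of the 1779 listed genes rose. At day 7 the share was 63.5% of 1717 genes (1090 rose, 627 fell), at day 10 73.9% of 2290 (1693 rose, 597 fell) and at day 14 74.4% of 2823 (2100 rose, 723 fell), all as listed in the authors' deposited tables. Rises of at least 8-fold numbered 210, 320, 471 and 661 at days 4, 7, 10 and 14, against 42, 50, 68 and 45 falls of that size. Among genes at or above the median abundance of each table, the share that rose was 42.8% at day 4, 57.2% at day 7, 68.6% at day 10 and 64.7% at day 14.

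**Figure D1:**
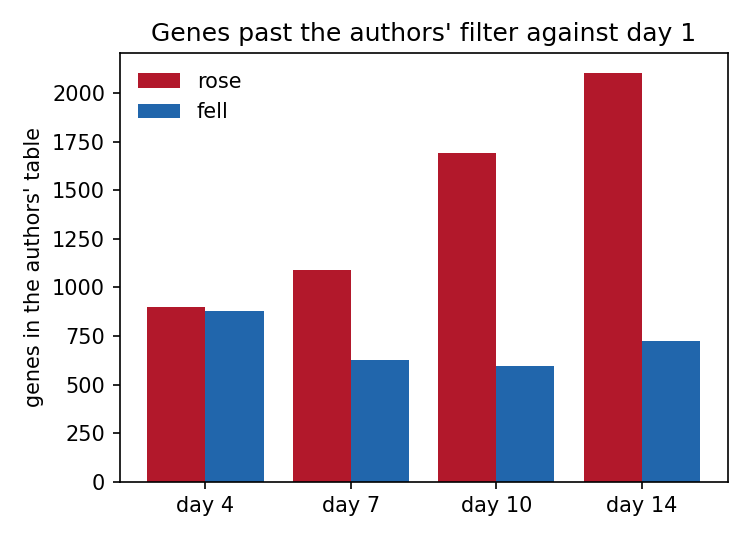
Bars give the number of genes listed in the authors' deposited tables as higher or lower than day 1 (vertical axis, genes) at days 4, 7, 10 and 14 (horizontal axis). Genes that rose went from 899 at day 4 to 2100 at day 14, while genes that fell numbered 880, 627, 597 and 723.

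The day 4 comparison is the earliest one. Its reference, day 1, is itself a day of differentiation, so changes before day 1 cannot be seen. Genes of the primitive streak, the structure through which mesoderm forms in the embryo, rose steeply. Tbx6 (Entrez Gene 21389), a transcription factor of paraxial mesoderm, rose from 2.47 to 669 TPM, 271-fold higher (201 to 375). The mesoderm-inducing ligand Wnt3a (22416) rose from 0.40 to 104 TPM, 259.8-fold higher (126 to 647), and Mesp1 (17292), an early marker of cardiac mesoderm, rose from 1.26 to 94.3 TPM, 74.7-fold higher (49.2 to 119). Of the 20 genes on the primitive streak and early mesoderm list, 12 rose, 1 fell and 7 were not listed in the authors' deposited table. This share of rising genes exceeded that of the other listed genes (Fisher's exact test, two-sided, adjusted p = 0.0273). Mixl1, a homeobox gene of the streak, rose from 4.82 to 221 TPM, 45.8-fold higher (37 to 57.6), and the apelin receptor gene Aplnr rose from 0.46 to 51 TPM, 111-fold higher (56.2 to 258).

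Hox genes, which set position along the body axis, rose together at day 4: 19 rose and 0 fell in the authors' deposited table (Fisher's exact test, two-sided, adjusted p = 0.000106). Hoxb3 rose from 0 to 14.9 TPM, at least 86.7-fold higher, and Hoxb1 rose from 1.55 to 78.9 TPM, 50.9-fold higher (34.9 to 77.5). Genes listed at day 4 had a mean count of at least 13 on the higher side. A gene at or near 0 tags at day 1 therefore could not be listed as fallen. Hoxb3, Hoxb4, Hoxd4 and Hoxa3 were at 0 TPM at day 1. For such genes 0 falls follow from the day 1 level, and the test cannot decide whether the list differs in direction. This limit holds for the Hox tests at the later days as well. Cdx2, a regulator of posterior Hox genes, rose from 4.94 to 235 TPM, 47.7-fold higher (38.6 to 59.7). Cell cycle genes moved the other way, with 1 risen, 12 fallen and 19 of 32 not listed in the authors' deposited table (Fisher's exact test, two-sided, adjusted p = 0.0160). Among them, the G1/S cyclin gene Ccne1 fell from 52.4 to 14.4 TPM, 3.63-fold lower (3.20 to 4.13). The ribonucleotide reductase subunit gene Rrm2 fell from 205 to 68.5 TPM, 2.99-fold lower (2.82 to 3.18) and the mitotic kinase gene Plk1 fell from 157 to 56.3 TPM, 2.79-fold lower (2.61 to 2.98).

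Several signalling lists held more rises than falls at day 4 without passing the test. Of 24 BMP pathway genes, 7 rose and 0 fell in the authors' deposited table (exact adjusted p = 0.0871). There, 11 Wnt pathway genes rose and 3 fell (exact adjusted p = 0.187), and 6 Notch pathway genes rose and 1 fell (exact adjusted p = 0.224). The homeobox gene Msx1, a BMP target, rose from 6.26 to 159 TPM, 25.4-fold higher (21 to 31), and the Wnt agonist gene Rspo3 rose from 2.93 to 55.6 TPM, 19-fold higher (14.4 to 25.6). The Notch ligand gene Dll3 rose from 3.04 to 98 TPM, 32.2-fold higher (24.5 to 43.1). Glycolysis genes gave 5 rises and 0 falls in the authors' deposited table (exact adjusted p = 0.187). Among them were the phosphofructokinase gene Pfkp (34.3 to 289.5 TPM) and the glucose transporter gene Slc2a3 (206 to 675 TPM). Immediate early and heat shock genes gave 1 rise and 5 falls (exact adjusted p = 0.224). The chaperone gene Hsp90aa1 fell from 845 to 319.7 TPM. Ribosomal protein genes gave 6 rises and 1 fall in the authors' deposited table (exact adjusted p = 0.224).

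Pluripotency genes, markers of undifferentiated cells, held more falls than rises at day 4. Of the 30 on the list, 1 rose, 8 fell and 21 were not listed in the authors' deposited table, which did not pass the test (exact adjusted p = 0.0998) but did among genes changed at least 4-fold (exact adjusted p = 0.0191). Pou5f1 (18999), the gene for the pluripotency factor Oct4, fell from 1489 to 678 TPM, 2.20-fold lower (2.15 to 2.24). Sox2 fell from 79.3 to 22.4 TPM, 3.54-fold lower (3.20 to 3.92), and the de novo DNA methyltransferase gene Dnmt3b fell from 264 to 41.8 TPM, 6.32-fold lower (5.90 to 6.78). The growth factor gene Fgf4 was the member that rose, from 9.53 to 29.99 TPM, 3.15-fold higher (2.65 to 3.75). The steepest falls among the more abundant genes were Gng3, a G protein subunit gene, from 57.7 to 4.56 TPM, 12.6-fold lower (10.3 to 15.6), and the lectin gene Cd209c, from 517 to 47 TPM, 11-fold lower (10.3 to 11.7). The endocytic receptor gene Lrp2 fell from 58.1 to 5.63 TPM, 10.3-fold lower (8.61 to 12.5).

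Among markers of other cell types at day 4, 1 neural gene rose and 5 fell (exact adjusted p = 0.224). Of the 14 neural genes listed at any day, 42.9% were listed at day 4, against 42.2% of all genes listed at any day (exact test of representation, adjusted p = 1.00). There were 3 epithelial genes and 2 epicardial and fibroblast genes that rose, and 1 gene of the endothelial and blood list and 1 endoderm gene rose in the authors' deposited table. The neurofilament gene Nefl fell from 11.3 to 0.90 TPM, 12.6-fold lower (8.03 to 20.9), while the blood and endothelial regulator gene Lmo2 rose from 1.78 to 73.3 TPM, 41.2-fold higher (28.9 to 60.8). Among genes at or above the median abundance, the streak and cell cycle calls were lost (exact adjusted p = 0.127 for each), and the streak call was also lost among genes changed at least 4-fold (exact adjusted p = 0.535).

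The day 7 comparison, between the early mesoderm stage and the cardiac stages, shows matrix genes rising and pluripotency genes falling. Extracellular matrix genes gave 16 rises, 0 falls and 14 of 30 not listed in the authors' deposited table (Fisher's exact test, two-sided, adjusted p = 0.0147). Fn1 (14268), the gene for the matrix and adhesion protein fibronectin, rose from 23.1 to 264 TPM, 11.4-fold higher (10.3 to 12.6), and the metalloproteinase inhibitor gene Timp3 rose from 9.07 to 58.9 TPM, 6.50-fold higher (5.51 to 7.71). Hox genes gave 24 rises and 0 falls (Fisher's exact test, two-sided, adjusted p = 0.000442). Hoxd10 rose from 0 to 93.9 TPM, at least 545-fold higher, and Hoxc6 from 0 to 43.1 TPM, at least 250.4-fold higher. Of the pluripotency genes, 0 rose and 10 fell in the authors' deposited table (Fisher's exact test, two-sided, adjusted p = 0.000725). L1td1, an RNA-binding protein gene of embryonic stem cells, fell from 189 to 5.05 TPM, 37.4-fold lower (31.1 to 45.3). Gdf3 fell from 27.7 to 1.88 TPM, 14.7-fold lower (10.8 to 20.5), and Pou5f1 fell from 1489 to 235 TPM, 6.34-fold lower (6.16 to 6.53).

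Smooth muscle contractile genes were listed at day 7, with 5 of 12 risen and 0 fallen in the authors' deposited table (exact adjusted p = 0.281). The smooth muscle actin gene Acta2 (11475) rose from 1.95 to 137 TPM, 70.1-fold higher (50.1 to 101). The calponin gene Cnn1 rose from 3.73 to 77.3 TPM, 20.7-fold higher (16.2 to 26.9), and Tagln, which had fallen at day 4, rose from 16.6 to 164 TPM, 9.88-fold higher (8.76 to 11.2). Acta2 and Tagln are also on the list of TGF-β target genes, of which 11 rose and 0 fell (exact adjusted p = 0.0605, not passing). The mesenchymal transcription factor gene Twist1 rose from 2.87 to 75.9 TPM, 26.4-fold higher (19.97 to 35.8). Among heart muscle genes, 6 cardiac transcription factor genes rose and 0 fell (exact adjusted p = 0.197), and 4 of 30 sarcomere genes rose in the authors' deposited table. Of the members listed at any day these were 46.2% and 25%, against 40.8% of all genes (exact test of representation, adjusted p = 0.916 and 0.658). Gata4 (14463) rose from 0 to 3.43 TPM, at least 19.9-fold higher. Isl1, a marker of second heart field progenitors, rose from 0 to 3.21 TPM, at least 18.7-fold higher, and Hand1 rose from 0.12 to 5.35 TPM, 46.6-fold higher (12.6 to 389).

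Glycolysis genes listed at day 7 were mostly others than those listed at day 4, with 1 gene risen and 5 fallen in the authors' deposited table (exact adjusted p = 0.121, not passing). The enzyme genes Tpi1 (727 to 275 TPM), Pgam1 (912 to 353 TPM) and Aldoa (1052 to 423 TPM) each fell. Pfkp rose at day 7 as at day 4, from 34.3 to 89.1 TPM, 2.60-fold higher (2.37 to 2.85). Neural crest and neural genes split, with 3 risen and 6 fallen (exact adjusted p = 0.193). Pax3, a gene of neural crest and somites, rose from 0 to 44.8 TPM, at least 260.4-fold higher, and the neuronal gene Stmn2 fell from 149 to 12 TPM, 12.4-fold lower (10.9 to 14). Streak genes remained high in part, 9 risen and 2 fallen in the authors' deposited table (exact adjusted p = 0.462), with Tbx6 from 2.47 to 153 TPM, 61.9-fold higher (45.8 to 85.7). Cell cycle genes gave 1 rise and 6 falls (exact adjusted p = 0.0676). The retinoic acid pathway gave 6 rises and 0 falls (exact adjusted p = 0.197), among them the binding protein gene Crabp1, from 2.12 to 48.1 TPM, 22.6-fold higher (16.3 to 32.3).

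Endothelial and blood genes numbered 4 risen and 1 fallen at day 7 (exact adjusted p = 0.746). The vascular cadherin gene Cdh5 rose from 0 to 6.98 TPM, at least 40.5-fold higher, and the blood regulator gene Runx1 from 0 to 11.4 TPM, at least 66.2-fold higher. Epithelial genes gave 4 rises and 1 fall in the authors' deposited table (exact adjusted p = 0.746), among them the keratin gene Krt18, from 5.97 to 95.9 TPM, 16.1-fold higher (13.2 to 19.8). Among genes at or above the median abundance, the matrix call (exact adjusted p = 0.127) and the Hox call (exact adjusted p = 0.153) were lost. The matrix call was also lost among genes changed at least 4-fold (exact adjusted p = 0.535). No listed matrix or Hox gene fell at day 7, so all those left under these limits rose. The lists left were too short to pass as rising.

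At day 10 sarcomere and cardiac transcription factor genes were listed as higher, as were single markers of vessels and blood. The sarcomere list gave 11 rises, 0 falls and 19 genes not listed in the authors' deposited table, and the cardiac transcription factor list gave 11 rises, 0 falls and 11 not listed. Neither passed in a table where 73.9% of all genes rose (exact adjusted p = 0.187 for each). The slow troponin I gene Tnni1 (21952) rose from 0 to 41.6 TPM, at least 242-fold higher. The atrial light chain genes Myl4 (17896) and Myl7 (17898) rose from 0 to 32.8 TPM, at least 190.3-fold higher, and from 0 to 29.7 TPM, at least 173-fold higher. The cardiac troponin T gene Tnnt2 (21956) rose from 0 to 8.78 TPM, at least 51-fold higher. Gata4 stood at 14.2 TPM and Isl1 at 11.4 TPM. The sodium-calcium exchanger gene Slc8a1, one of 5 calcium handling and ion channel genes that rose (exact adjusted p = 0.462), rose from 0.63 to 50.6 TPM, 80.1-fold higher (44.6 to 161).

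Genes of some other lineages were listed as well at day 10. Of the endothelial and blood list, 10 rose and 1 fell in the authors' deposited table (exact adjusted p = 0.455), and the embryonic globin gene Hba-x (15126) rose from 0 to 118 TPM, at least 685-fold higher. Nr2f2, a venous and atrial transcription factor gene, rose from 0 to 66.1 TPM, at least 384-fold higher, and the semaphorin and VEGF co-receptor gene Nrp1 rose from 0 to 61.7 TPM, at least 358-fold higher. Too few genes were listed for a test of the next lists. There were 4 endoderm genes that rose, such as Sox17 at 0 to 8.74 TPM. Risen too were 3 epicardial and fibroblast genes, such as Tbx18 at 0 to 9.52 TPM, and 4 smooth muscle genes, such as Acta2 at 1.95 to 63.1 TPM. Neural genes gave 4 rises and 5 falls (exact adjusted p = 0.187), and epithelial genes 2 rises and 3 falls (exact adjusted p = 0.224).

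The pluripotency list gave 0 rises and 11 falls at day 10 in the authors' deposited table (Fisher's exact test, two-sided, adjusted p = 1.59e-05). Pou5f1 fell from 1489 to 117 TPM, 12.7-fold lower (12.2 to 13.2), and L1td1 from 189 to 3.76 TPM, 50.3-fold lower (40.6 to 63). Matrix genes gave 18 rises and 0 falls (exact adjusted p = 0.0414). The proteoglycan gene Vcan rose from 1.78 to 33.5 TPM, 18.8-fold higher (13.1 to 27.9). Hox genes gave 24 rises and 0 falls (exact adjusted p = 0.0160), and Hoxd10 stood at 102 TPM. Of 17 Nodal and activin pathway genes, 4 fell, 1 rose and 12 were not listed, which did not pass the test (exact adjusted p = 0.0962). The mesendoderm ligand gene Nodal fell from 86.2 to 8.74 TPM, 9.86-fold lower (8.50 to 11.5). Brachyury, the gene T (20997), fell from 156 to 18.6 TPM, after 701 TPM at day 4 (a value chosen after it was seen). Cell cycle genes gave 2 rises and 2 falls in the day 10 table, too few listed for a test. The streak list gave 5 rises and 5 falls (exact adjusted p = 0.246). Among genes at or above the median abundance, the matrix call (exact adjusted p = 0.144) and the Hox call (exact adjusted p = 0.249) were lost. Both were also lost among genes changed at least 4-fold (exact adjusted p = 0.535 and 0.0672). All members left under these limits rose, and the lists left were too short to pass as rising.

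Some immediate early genes, which respond within minutes to growth factors and stress, were listed as higher at day 10, in a list that did not pass the test. Fosb rose from 0.34 to 41.6 TPM, 121-fold higher (55.3 to 329.9). Fos rose from 1.38 to 94.4 TPM, 68.5-fold higher (45.9 to 107), and Jun rose from 10.1 to 91.6 TPM, 9.06-fold higher (7.77 to 10.6). Egr1, lower than day 1 at days 4 and 7, rose from 77.7 to 263 TPM, 3.39-fold higher (3.19 to 3.596). With the heat shock genes of the same list, 5 rose and 2 fell in the authors' deposited table (exact adjusted p = 1.00). The imprinted growth genes H19 and Igf2 rose from 2.70 to 697 TPM, 259-fold higher (194 to 352), and from 15 to 2147 TPM, 143-fold higher (127 to 163). In all, 11 imprinted genes rose and 0 fell (exact adjusted p = 0.187).

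At day 14, when beating was seen, sarcomere genes were among the largest changes in the whole table. Myl7 rose from 0 to 267 TPM, at least 1552-fold higher, and Myl4 rose from 0 to 93.2 TPM, at least 541-fold higher. Tnnt2 rose from 0 to 66.7 TPM, at least 388-fold higher, and Myh7 (140781), the gene for the slow myosin heavy chain, rose from 0 to 53.5 TPM, at least 311-fold higher. The sarcomere list gave 14 rises, 0 falls and 16 genes not listed in the authors' deposited table, which did not pass where 74.4% of all genes rose (exact adjusted p = 0.121). Cardiac transcription factors gave 13 rises, 0 falls and 9 not listed (exact adjusted p = 0.175). Nkx2-5 (18091), a core cardiac homeobox gene, was listed at day 14 alone, from 0.12 to 4.57 TPM, 39.8-fold higher (10.8 to 333). The alpha myosin heavy chain gene Myh6 (17888) was also listed at day 14 alone, from 0 to 3.27 TPM, at least 19-fold higher.

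**Figure D2:**
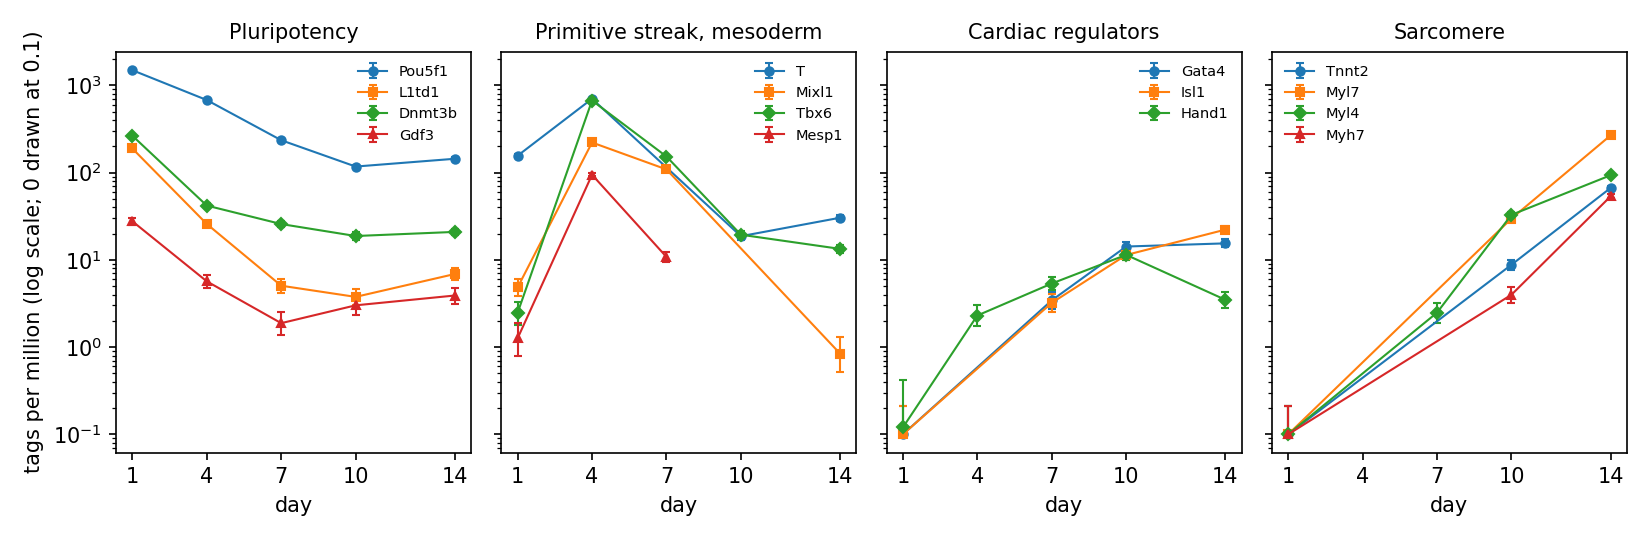
Points show the authors' mean TPM (vertical axis, log scale, with 0 drawn at 0.1) against day of differentiation (horizontal axis) for pluripotency, primitive streak, cardiac transcription factor and sarcomere genes, with 95% counting intervals as error bars, and lines join the days at which a gene was listed. Pou5f1 went from 1489 TPM at day 1 to 144 at day 14, Tbx6 reached 669 at day 4, and Myl7 reached 267 at day 14.

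The non-cardiac lineage lists with enough genes for the test did not pass the test of direction at day 14, though single markers rose steeply. They had at most 10 genes listed, in a table where 74.4% of all genes rose. Lists of that length could not pass as rising, so the result does not speak against a rise. Epicardial and fibroblast genes gave 7 rises and 0 falls in the authors' deposited table (exact adjusted p = 0.324). The epicardial genes Tbx18 and Tcf21 rose from 0 to 24.2 TPM, at least 140.3-fold higher, and from 0 to 13.5 TPM, at least 78.4-fold higher. The retinoic acid synthesis gene Aldh1a2 rose from 0.12 to 61.8 TPM, 538-fold higher (149 to 4446). Endothelial and blood genes gave 7 rises and 1 fall (exact adjusted p = 0.746), and endoderm genes 6 rises and 0 falls (exact adjusted p = 0.462). Smooth muscle genes gave 5 rises and 0 falls (exact adjusted p = 0.462), and neural genes 7 rises and 3 falls (exact adjusted p = 0.765). Hba-x was at 26.7 TPM, below its day 10 level, while the liver and yolk sac apolipoprotein gene Apob rose from 0 to 10.7 TPM, at least 61.9-fold higher. Of the 14 skeletal muscle genes, 0 were listed at any day in the authors' deposited tables.

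Matrix genes gave 20 rises and 0 falls at day 14 in the authors' deposited table (Fisher's exact test, two-sided, adjusted p = 0.0282). The type I collagen gene Col1a2 rose from 0.12 to 30.5 TPM, 266-fold higher (73.4 to 2201). Hox genes gave 22 rises and 0 falls (exact adjusted p = 0.0207). Pluripotency genes gave 0 rises and 11 falls (exact adjusted p = 1.59e-05), with L1td1 from 189 to 6.88 TPM, 27.4-fold lower (23.5 to 32.3). Cell cycle genes gave 2 rises and 7 falls (exact adjusted p = 0.0160). Plk1 fell from 157 to 48.4 TPM, 3.25-fold lower (3.03 to 3.48). The D-type cyclin genes Ccnd1 and Ccnd2 rose from 25.4 to 76.3 TPM, 3.00-fold higher (2.70 to 3.34), and from 58.4 to 215 TPM, 3.67-fold higher (3.43 to 3.93). Cell cycle inhibitors gave 5 rises and 1 fall (exact adjusted p = 1.00), with Cdkn1b at 15.6 to 41.9 TPM. Imprinted genes gave 11 rises and 0 falls (exact adjusted p = 0.187). H19 rose from 2.70 to 1187 TPM, 440.1-fold higher (331 to 599), and Igf2 from 15 to 3243 TPM, 216-fold higher (192 to 245).

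Fatty acid oxidation and mitochondrial energy genes gave 5 rises and 0 falls at day 14 in the authors' deposited table (exact adjusted p = 0.462), with the mitochondrial enzyme gene Idh2 at 50.4 to 199 TPM. Histone genes gave 6 rises and 0 falls (exact adjusted p = 0.462). Both lists were too short to pass as rising at day 14. The streak list gave 5 rises and 6 falls (exact adjusted p = 0.143). Among genes changed at least 4-fold, 1105 rose and 159 fell. There the streak list passed with a lower share of rises than the other listed genes (exact adjusted p = 0.00678). Among genes at or above the median abundance, the matrix call (exact adjusted p = 0.0702) and the cell cycle call (exact adjusted p = 0.0972) were lost. Among genes changed at least 4-fold, the matrix call (exact adjusted p = 0.535) and the Hox call (exact adjusted p = 0.452) were lost. No listed matrix or Hox gene fell at day 14, so all those left under these limits rose. Where a call was lost, the list left was too short to pass as rising, which does not speak against a rise.

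Genes of the TGF-β pathway, the subject of the study, were followed over all 4 comparisons. The list of TGF-β ligands, receptors and SMADs gave 2 rises and 1 fall at day 4, 6 and 1 at day 7, 8 and 1 at day 10, and 10 and 1 at day 14 in the authors' deposited tables. It passed at none of the 3 days tested (exact adjusted p = 0.557, 0.562 and 0.455). The type I receptor gene Tgfbr1 (21812) was listed at day 14 alone, from 48.9 to 145 TPM, 2.96-fold higher (2.74 to 3.19). The type II receptor gene Tgfbr2 (21813) rose at day 10, from 0.98 to 5.59 TPM, 5.73-fold higher (3.44 to 10.1), and at day 14, from 0.98 to 5.33 TPM, 5.46-fold higher (3.28 to 9.67). The receptor-activated Smad3 (17127) rose at days 7, 10 and 14, to 52.3, 52.1 and 49.3 TPM from 17.7 TPM. The inhibitory Smad7 (17131) was listed at day 10 alone, from 41.9 to 100.3 TPM, 2.39-fold higher (2.20 to 2.61). The co-receptor gene Tgfbr3 fell at all 4 days, at day 4 from 23.5 to 7.21 TPM, 3.26-fold lower (2.72 to 3.93). The latent TGF-β binding protein gene Ltbp3 rose at day 14, from 6.37 to 56.5 TPM, 8.87-fold higher (7.30 to 10.9). Smad2 and Smad4, which carry the signal to the nucleus, were not listed at any day. TGF-β target genes gave 5 rises and 2 falls at day 4 (exact adjusted p = 0.562), 10 and 0 at day 10 (exact adjusted p = 0.187), and 9 and 0 at day 14 (exact adjusted p = 0.224). BMP pathway genes gave 8, 10 and 11 rises at days 7, 10 and 14 and 0 falls (exact adjusted p = 0.121, 0.187 and 0.187). At days 10 and 14 the TGF-β target and BMP lists were too short to pass as rising. Those results do not speak against a rise.

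Genes of the primary cilium mostly rose where they were listed: 5 rose and 1 fell at day 4, 6 and 0 at day 7, 9 and 0 at day 10, and 10 and 0 at day 14 of 52 genes in the authors' deposited tables. The list passed at no day (exact adjusted p = 0.338, 0.197, 0.224 and 0.187). At days 7, 10 and 14 each listed gene rose, yet the exact p before adjustment was 0.0920, 0.123 and 0.0736. Lists of that length could not pass as rising in these comparisons, so the result does not speak against a rise. The ciliary kinesin gene Kif3a rose to 66 TPM at day 14, 3.27-fold higher (2.91 to 3.68), and the retrograde dynein gene Dync2h1 was 4.48-fold higher at day 7 (3.77 to 5.36). Ift88, an intraflagellar transport gene, was not listed. Hedgehog pathway genes, whose signal runs through the cilium, gave 7 rises and 0 falls at day 10 (exact adjusted p = 0.324). At day 14 they gave 8 and 0 (exact adjusted p = 0.338). This list, too, was too short to pass as rising at either day. The co-receptor genes Gas1 and Boc rose from 12.7 to 190.0 TPM, 15-fold higher (13.1 to 17.2), and from 1.95 to 43.9 TPM, 22.5-fold higher (16 to 32.7). Endocytosis genes split, with 2 risen and 4 fallen at day 4 and 7 risen and 2 fallen at day 14 of 39 in the authors' deposited tables (exact adjusted p = 0.562 and 1.00). The caveolin gene Cav1 rose at day 14 from 0 to 61.3 TPM, at least 356-fold higher, and the clathrin adaptor gene Dab2 rose from 9.64 to 141 TPM, 14.6-fold higher (12.5 to 17.1). The early endosome gene Eea1 (216238) was listed at day 14 alone, from 12.7 to 26.9 TPM, 2.11-fold higher (1.81 to 2.47). The recycling gene Ehd3 fell from 90.3 to 12.9 TPM, 7.02-fold lower (6.20 to 7.95). The clathrin heavy chain gene Cltc was not listed at any day.

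**Figure D3:**
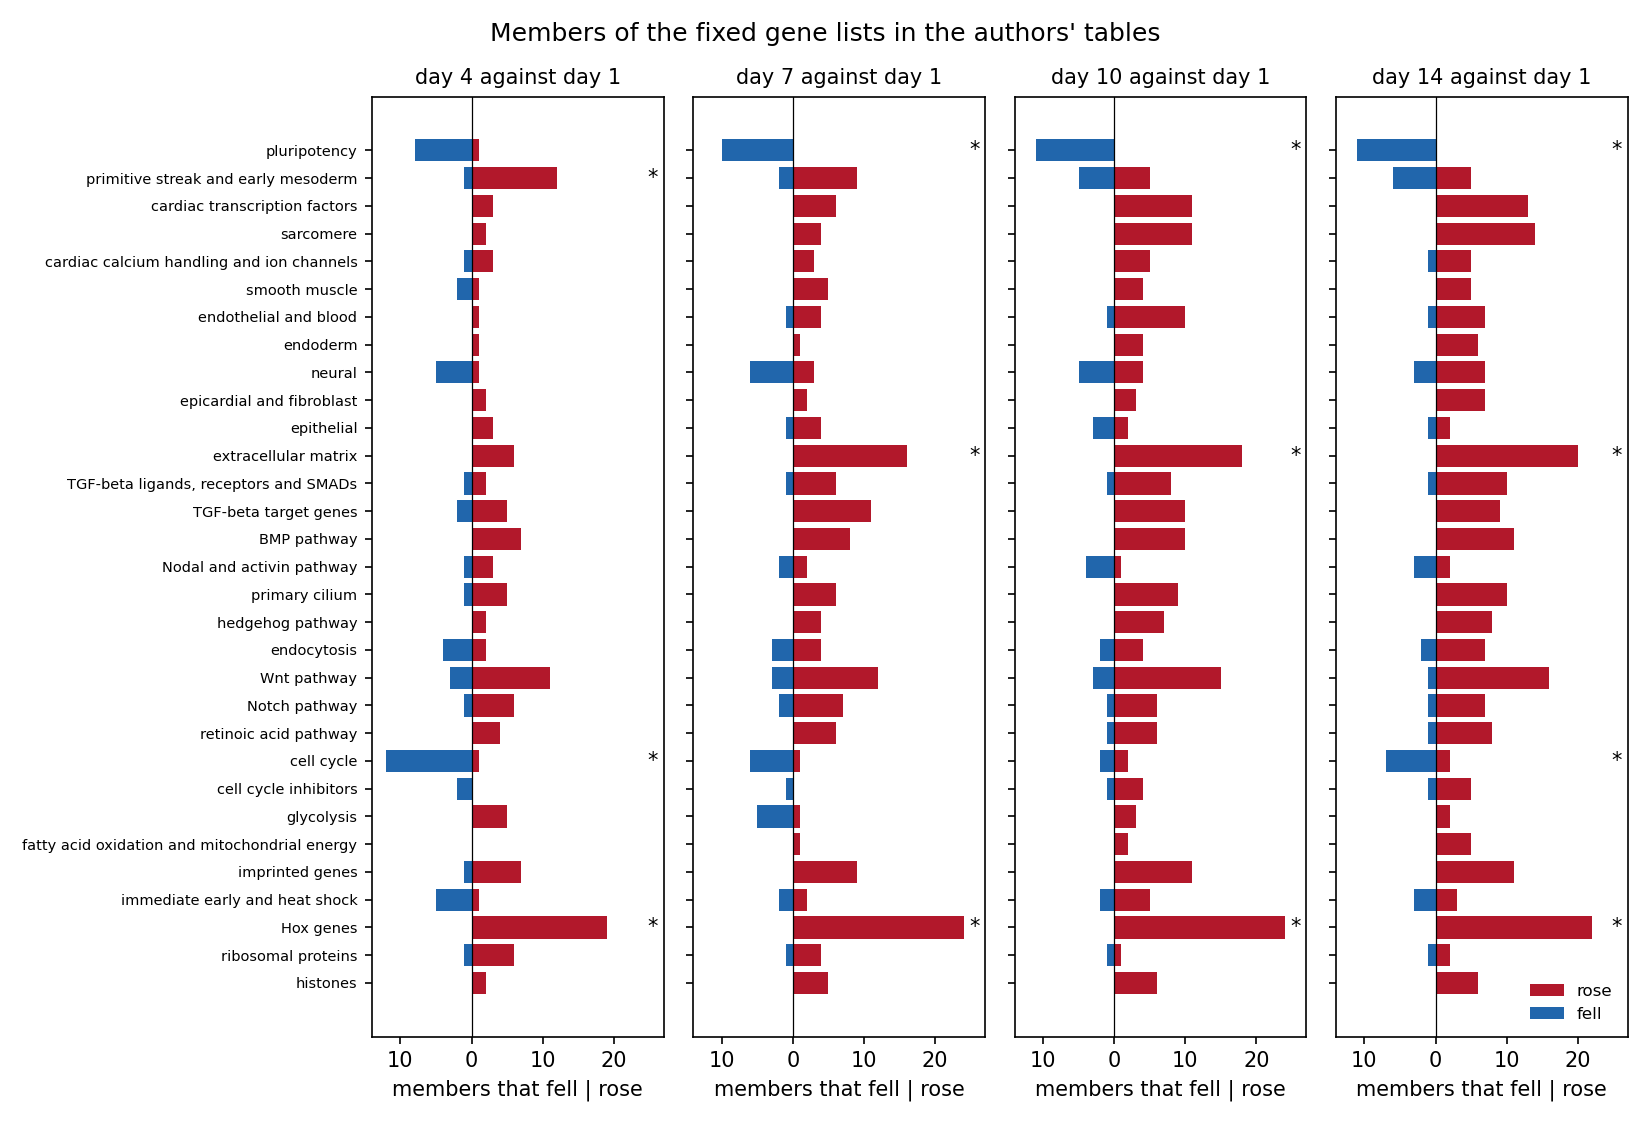
For each gene list and day, bars show how many members fell (left) or rose (right) against day 1 (horizontal axis, genes) in the authors' deposited tables, with an asterisk where the list's share of rises passed Fisher's exact test after adjustment. Hox genes rose 19, 24, 24 and 22 times at days 4, 7, 10 and 14 with 0 falls, and pluripotency genes fell 8, 10, 11 and 11 times.

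Across the 90 tests of direction, 13 passed. Where every listed member rose and the exact p before adjustment still lay above 0.05, the list was too short to pass as rising. This was so for cardiac transcription factor, sarcomere and imprinted genes at day 10, among others, and does not speak against a rise. The Hox passes carry the limit given at day 4 for genes near 0 tags at day 1. A separate test asked whether a list was listed more or less often at a day than the other genes listed at any day, and 9 of 124 such tests passed. Primitive streak genes were over-represented at day 4 (Fisher's exact test, two-sided, adjusted p = 0.0326), Hox genes at days 4, 7 and 10 (exact adjusted p = 0.0332, 6.05e-06 and 0.00235), matrix genes at days 7, 10 and 14 (exact adjusted p = 0.0145, 0.0269 and 0.0145), and endothelial and blood genes at day 10 (exact adjusted p = 0.0287). Glycolysis genes were under-represented at day 14, with 2 of the 10 listed at any day (exact adjusted p = 0.0431). Genes are not independent replicates, so these p-values describe the lists within these tables.

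Many of the genes were shared between days. Of 4213 genes listed at any day in the authors' deposited tables, 579 were listed at all 4, of which 372 rose each time, 197 fell each time and 10 changed direction. Days 10 and 14 shared 1813 genes, 1381 rising at both and 432 falling at both, where independent lists would share 844 and 102. Days 4 and 7 shared 827 genes, 481 rising at both and 333 falling at both, where independent lists would share 233 and 131. In unchanged groups simulated against the same day 1 libraries, a mean of 146 genes reached 2-fold at both of these days by counting error, and 0.10 did so at the abundance of the listed genes. Over the 6 pairs of days, 95.8% to 100% of the shared genes had the same direction, against 96.7% to 97.2% of the simulated genes of any abundance that reached 2-fold at both days. Nearly all of those simulated genes lay below the abundance of the listed genes, so their share does not measure chance agreement among the listed genes. Part of the excess may come from the shared day 1 libraries, which could not be split because the tables hold 0 columns with values of a single library. Day 14 held 712 genes listed at no other day, of which 584 rose, and day 4 held 591, of which 242 rose. Over the days, the median log2 change of the listed sarcomere genes went from 2.62 at day 4, where it rests on 2 genes, to 6.30 at day 14, where it rests on 14, with genes at 0 tags set at their floor. The median of the listed streak genes went from 4.96 to -2.36, and that of the listed pluripotency genes from -2.29 to -3.37. Among the 5 streak genes listed at all 4 days, the median went from 4.96 to 2.43. Among streak genes not in that set, T and Mixl1 (chosen after their values were seen) were above day 1 at day 4 and below it at day 14, T at 701 and 30.4 TPM and Mixl1 at 221 and 0.84 TPM. Nanog, a core pluripotency gene, and Actc1, the cardiac actin gene, were not listed at any day, and Sox2 was listed at day 4 alone.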

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

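The tests in this part were chosen before the result each one measures was seen, except the list of genes with opposite directions, the levels of further immediate early genes and the minimum of 10 tags on each side, which were chosen after the tables had been seen.

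Across the deposited tables, 55 genes rose at one later day and fell at another against day 1. Of these, 41 fell first and rose later, and 14 rose first and fell later. Such genes differ at least 4-fold between the days by how they were picked, so no test is given, and the spread between replicates is not known. The 10 genes given here have the largest ratios between days among genes with tags at both days. The streak gene Mixl1 differed by a log2 ratio of -8.04 between day 14 and day 4, and Brachyury, the gene T, by -5.23 between day 10 and day 4. The unnamed transcript 6030429G01Rik differed by -4.66 between day 14 and day 4. The others were lower at day 4 and higher later. Gm98 differed by a log2 ratio of 6.67, the muscle filament gene Nexn by 5.94 and the splicing regulator gene Mbnl1 by 4.97 between day 14 and day 4. The synaptic gene Nrgn differed by 5.02, the glypican gene Gpc4 by 4.88 and the immediate early gene Nr4a1 by 4.61 between day 10 and day 4, and the smooth muscle gene Tagln by 4.51 between day 7 and day 4.

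The first pattern weighed is the rise of some immediate early genes at day 10, on a list that did not pass its test. Sustained ERK signalling at day 10 stays open: 0 of 10 ERK feedback genes rose at day 10, 2 fell (Etv5 and Etv4) and the others were not listed. A bound of fewer than 2 rises had been set as evidence against it, which was wrong, since a filtered table leaves out genes it could not call. A handling or medium stimulus shortly before lysis at day 10 stays open too: 7 of 15 further immediate early genes rose at day 10, against 4 at day 7 and 4 at day 14. These counts met the bound set beforehand as support, a minimum of rises at day 10 and more than at days 7 and 14. The levels, compared afterwards for genes listed at both days, go both ways. Egr4 and Btg2, listed as higher at day 10 alone, do not enter that comparison. Of the 4 listed at both days 7 and 10, 1 was higher at day 10 (Klf6) and 3 were lower (Gem, Ier5 and Klf10). Of the 4 listed at both days 10 and 14, 2 were higher at day 10 (Ier5 and Zfp36) and 2 were lower (Gem and Klf6). The differences between the days were not tested. Whether 1 of the 4 day 10 libraries carries the rise cannot be told apart from a rise in all of them, since 0 columns hold values of a single library, and the day of differentiation stays open and untested.

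The second pattern is the fall of 5 glycolytic genes at day 7, a list that did not pass its test. A few genes taking most of the tags at day 7 could be weighed for the listed genes alone, which held too few tags for it. Listed genes that rose held 4.39% of the day 7 tags, where a common fall of 2-fold needs at least 50%. All genes listed at day 7 together held 6.54% of these tags, so that bound was out of reach. The test cannot decide the question for genes that are not listed, which have no value. A lower hypoxia response at day 7 could not be decided: of the listed hypoxia genes outside glycolysis, 50% fell (2 rose, 2 fell), and 4 genes are too few. The day of differentiation stays open as an untested biological explanation.

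The third pattern is the excess of rises over falls at days 7, 10 and 14. A loss of tags from abundant genes that lifts all others could be weighed for the listed genes alone, which held too few tags for it. Genes that fell at day 14 lost 4.87% of all tags, where a common rise of 2-fold needs at least 50%. All genes listed at day 14 together held 9.90% of the day 1 tags, so that bound was out of reach. The test cannot decide the question for losses from genes that are not listed, which have no value. Genes at or near 0 tags at day 1 as the whole cause are argued against. With at least 10 tags on each side, 59.4%, 70.6% and 70.2% of genes rose at days 7, 10 and 14. The 95% binomial intervals were 56.8% to 61.9%, 68.5% to 72.6% and 68.3% to 72.0%. Of all listed genes, 63.5%, 73.9% and 74.4% rose. These intervals treat genes as independent. They leave out the error between replicates and that of the shared day 1 libraries. Genes with few day 1 tags above that minimum stay in. A test set beforehand, the 64.7% that rose at day 14 at or above the median abundance, decides nothing here, because abundance over both days keeps genes that rose from 0 tags, such as Myl7. Differentiation itself stays open and was not tested.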

How the results depend on the processing

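Changes of at least 2 on the log2 scale, log2(TPM + 1), genes with at least 1 tag on each side, shares by abundance, deposited ratios in the time course and symbols read from descriptions were chosen after the data were seen.

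Of 44 alternatives that could change a main comparison, 21 left the result in place and 23 moved it. The other 21, a log2 change of at least 1, every entry counted and the most abundant entry per symbol, could change nothing, because the smallest log2 change is 1.00 and symbols are repeated 0 times. At day 4 the balance of rises and falls turned over at or above the median abundance, with 381 rises and 509 falls against 899 and 880, and the share that rose was 49.0% among genes with at least 1 tag on each side. Restriction to genes at or above the median abundance left 890, 859, 1145 and 1412 listed genes at days 4, 7, 10 and 14, as its construction of keeping the upper part of each table implies. The shares that rose became 42.8%, 57.2%, 68.6% and 64.7%, and the lists that passed the direction test numbered 0, 1, 1 and 1, against 3, 3, 3 and 4. With that minimum of 1 tag, the share was 71.8% at day 10 and 71.8% at day 14. Absolute log2 changes of at least 2 left 501, 658, 996 and 1264 genes, 1 passing list at day 10 and 2 at day 14, and 171 genes shared by all 4 days against 579. Fewer genes tested is part of each alternative, and beyond that the cause was not tested. With all genes of the reference table as background, 101 of 128 tests of representation passed against 9, since genes never listed then count as measured. The median at day 14 lay above that at day 4 in 17 of 22 lists, and in 7 of 14 when only members listed at all 4 days were used, where the cause was not tested. Lists with fewer than 3 such members at either day were left out of these counts.

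Of the 13 passing list-and-day tests, 8 no longer passed at or above the median abundance, 3 still did and 2 had too few genes. With log2 changes of at least 2, 6 no longer passed, 5 still did and 2 had too few genes, while 2 others passed. In all, 9 of the 13 were lost under at least 1 of these. No listed matrix or Hox gene fell at any day. Where the calls of these lists were lost, the genes left all rose and were too few to pass. On the log2(TPM + 1) scale, 13 of 13 passed. On the log2(TPM + 1) scale, 285 named values stayed within their counting interval and 84 moved. Reading blank symbols from descriptions added 6 list members in 12 list-and-day pairs, and no call changed. Of these, Meis1 rose from 0.12 TPM (2 tags) to 10.7, 77.5 and 117 TPM at days 7, 10 and 14, Postn rose to 49.4 TPM, Tnc to 24.3 TPM, Csrp3 to 10.1 TPM and Dcn to 2.43 TPM at day 14, and Cldn7 fell from 8.90 to 1.36 TPM at day 4.

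No paired analysis was possible because the tables hold no values per library. For the same reason other count-based tests and normalizations, filters on low counts per library, a replicate block, leaving out each replicate and other splits of the samples were not run. Low counts were filtered only on the tag sums of a day, at 1 or 10 tags on each side. FDR limits of 0.01 and 0.001 were not run because the FDR column exceeds 1. With 5.72e+06 to 5.96e+06 tags per mean library, genes below a few tags at day 1 have wide counting intervals.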

Other observations

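The tests of added gene lists and of the authors' pathway column, the Hox comparison and the genes named in this part were chosen after the main tables had been seen.

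Hypoxia response genes, switched on when oxygen is short, rose at day 4. Outside glycolysis, 12 of 20 rose and 0 fell in the authors' deposited table (Fisher's exact test, two-sided, adjusted p = 0.00190). Ndrg1 went from 4.53 to 50.4 TPM and the oxygen sensor gene Egln3 from 9.01 to 74.4 TPM. At days 10 and 14, 8 and 9 rose and 0 fell at either day, without passing (exact adjusted p = 0.148 for each).

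Aminoacyl-tRNA synthetase genes, which load amino acids for translation, gave 6, 6, 9 and 6 falls at days 4, 7, 10 and 14 with 0 rises (exact adjusted p = 0.0218, 0.00560, 6.38e-05 and 0.00167), among them Lars at 311 to 96.5 TPM at day 10. Proteasome genes gave 8 falls at day 4 and 5 at day 14, with too few listed for a test at days 7 and 10 (exact adjusted p = 0.00705 and 0.00327). Further immediate early genes at day 10 and somite genes at day 10 did not pass (exact adjusted p = 0.219 and 0.335).

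In the authors' pathway column, 50 of 449 tests of direction passed, for pathways with at least 10 listed genes. In the Spliceosome pathway 3 rose and 26 fell at day 4 (exact adjusted p = 0.000245), and in Axon guidance 35 rose and 10 fell (exact adjusted p = 0.00419). ECM-receptor interaction genes rose at days 7, 10 and 14, and at day 14 53 rose and 3 fell (exact adjusted p = 0.00332). In the Dilated cardiomyopathy pathway 26 rose and 0 fell at day 10 (exact adjusted p = 0.00838), but at day 14, with 31 rises and 2 falls, it did not pass (exact adjusted p = 0.0624). Cardiac muscle contraction passed at neither day (exact adjusted p = 0.683 and 1.00).

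Txnip and Arrdc4, arrestin family genes that respond to glucose, fell at day 4 and rose at day 7. Txnip went from 5.91 TPM at day 1 to 0 at day 4 and 37 at day 7. Arrdc4 went from 11.7 TPM to 1.96, 42.7, 2.97 and 1.93 TPM at days 4, 7, 10 and 14.

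Hox genes of paralog groups 1 to 6 were listed earlier than those of groups 7 to 13. At day 4, 14 of 15 genes of groups 1 to 6 (93.3%) and 5 of 11 of groups 7 to 13 (45.5%) were listed, a difference of 47.9 percentage points (Fisher's exact test, two-sided, p = 0.0208). This is consistent with Hox collinearity, the opening of the clusters in order, as a hypothesis found and tested on the same data.

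Presomitic and somitic mesoderm in the cultures may account for part of the Tbx6 and Pax3 signal, but 2 of 15 somite genes, Foxc1 and Fgf17, rose at day 4 or 7, and 5 at day 10. Embryonic red cells in the cultures may account for Hba-x at day 10, and 2 of 14 further erythroid genes, Hbb-y and Alas2, rose at day 10. Both questions stay open. A bound of fewer than 3 somite genes had been set as evidence against somites, which was wrong, since a table that lists only genes past a filter leaves out genes it could not call.

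Part of the deposited P-Value and FDR columns lies above 1, where no probability can be. The P-Value does so for 214 of 1779 genes at day 4 and 354 of 2823 at day 14, and the FDR column reaches 9.82e+09 at day 4. The digits of the P-Value column match those of a two-sided counting test, within 0.02 on the log10 scale, for 53.4%, 39.3%, 29.9% and 30.3% of the genes compared at days 4, 7, 10 and 14, where 4% would match by chance.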
